A study of Homo sapiens with 6 samples.

How the data were processed

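RNA was profiled by sequencing in AsPC-1, an established human pancreatic cancer cell line, 48 h after transfection with a control siRNA (siControl) or an siRNA against OTUD4 (siOTUD4), per the labels. Each group held 3 libraries, named 1, r1 and r2. Total RNA was taken up in Trizol and libraries were made with an MGISEQ-2000RS protocol, per the labels' protocols. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

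The authors deposited 1 table of FPKM values per library (fragments normalised by transcript length and by mapped fragments), with 2 decimals, a gene symbol and an Entrez identifier for each of 16098 genes. The genome build was GRCh38.p13, per the submitters' processing notes. The aligner, the quantifier and the gene annotation are not given in the sources used here. FPKM values are not counts and do not sum to a fixed total, so a rise in the share of short, abundant transcripts raises the sum and lowers the values of other genes. Low values showed no regular steps from which relative depth could be read, so the depth of each library is unknown and no counting interval is given.

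Before averaging, the libraries of each group were compared. Pearson's r of log2(FPKM + 1) across tested genes, which are not independent replicates, was 0.9974 to 0.9983 within groups and 0.8842 to 0.8868 between groups. For the 1000 genes with the highest product of FPKM and transcript length, the squared difference between libraries of a group was 2.47 to 2.76 times (siControl) and 5.51 to 8.82 times (siOTUD4) that of weakly expressed genes after scaling for counting noise. This comparison looked only for one library deposited more than once, and found no pair within counting noise of that size, so each library was kept as 1 sample. It cannot tell separate cultures from separate preparations of one culture.

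From the FPKM values, log2(FPKM + 1) was computed for the 11212 genes with a mean of at least 1 FPKM over the 6 libraries. Fold changes on this scale understate the change of genes with low FPKM. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trended prior), with siOTUD4 minus siControl as the contrast and no covariate. P-values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. OTUD4 was also compared by an exact two-sided permutation test, for which 3 libraries against 3 allow no p below 0.1. All errors beside means are SDs over the 3 libraries of a group, and errors beside log2 fold changes are limma standard errors.

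Before the data were examined, 22 gene lists (513 different genes) were fixed: YAP/TAZ targets, Hippo pathway components, OTU deubiquitinases, S phase, G2/M phase, p53 targets, interferon-stimulated genes, NF-kB targets, epithelial and mesenchymal genes, classical and basal-like pancreatic tumour genes, the integrated stress response, endoplasmic reticulum chaperones, hypoxia and glycolysis, cholesterol synthesis, ERK pathway output, MYC targets, actin cytoskeleton and SRF targets, and markers of fibroblasts, leukocytes and endothelium. Of these genes, 34 had no match among the listed symbols. Some genes were in several lists, and LATS2, AMOTL2 and PTPN14 were in both the YAP/TAZ and the Hippo list. The 19 lists with at least 3 tested members were compared with all other tested genes by camera with a preset inter-gene correlation of 0.01, adjusted over the 19 lists. Camera with an estimated correlation and fry were run beside it. Fry tests whether the members of a list move one way on balance and does not compare the list with other genes.

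The genes named were also fixed by rule before the data were examined: OTUD4, YAP1, WWTR1, CCN1, CCN2, ANKRD1, LATS1 and LATS2, the 12 genes with the largest and the 12 with the smallest log2 fold change among genes past the threshold with no overlap between groups and a mean of at least 5 FPKM in the higher group, and up to 4 members of each list with the largest absolute log2 fold change. Other genes are named where a count of 5 or fewer called for it or as examples, and these were chosen after their values were seen. A few genes that the rule or a count would name are not reported here.

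The alternatives fixed beforehand were a pseudocount of 0.1, no filter on low values, a filter at a mean of 5 FPKM, rescaling to equal totals (TPM), median-of-ratios size factors, quantile normalization, the replicate name as a block, no trend in eBayes, an estimated inter-gene correlation, and leaving out each library in turn. After the data were seen, 2 corrections for transcript GC content and length were added. They used splines with 5 degrees of freedom and either the median over a gene's protein-coding transcripts or its longest one, taken from GENCODE 29 (GRCh38). GC content and length were found for 99.6% of the tested genes. Gene families defined by symbol pattern and 2 stress-response lists were also added after the data were seen. Gene coordinates are from GENCODE 29, and older symbols were matched through a RefSeq gene table.

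The fit was tested on simulated data for this comparison over 11112 genes, 50 of them changed at each of 4 fold sizes. It recovered 28 of 50 genes at 1.25-fold, 46 at 1.5-fold, 49 at 2-fold and 48 at 4-fold, and called 11 unchanged genes. The simulated changes were random in direction, with independent noise and no shift shared by many genes. The simulation therefore does not measure false calls under a broad shift such as that in the real data. Permutation tests and summaries were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots with matplotlib 3.10.9.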

Results

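Transcript levels were given as FPKM for 16098 genes in 6 libraries of AsPC-1 cells, 3 transfected with siControl and 3 with siOTUD4 for 48 h. The title of the series places OTUD4, a deubiquitinase of the OTU family, in pancreatic cancer and the Hippo/YAP axis, so the comparison of siOTUD4 with siControl was read first for OTUD4 and for genes of that pathway. The depth of the libraries is unknown. FPKM values summed to 636181, 638360 and 640545 in the siControl libraries and to 949644, 982902 and 946495 in the siOTUD4 libraries. Genes above 0 numbered 14624 to 14659 in siControl and 14052 to 14269 in siOTUD4 libraries. Ribosomal protein genes held 27.5% of the FPKM sum in each siControl library and 37.2% to 38.0% in the siOTUD4 libraries.

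OTUD4 (Entrez 54726), the target of the siRNA, was lower in all 3 siOTUD4 libraries. It is a protein-coding gene on the minus strand of chromosome 4, from 145110838 to 145180161 (GRCh38). Its level was 11.77 ± 0.197 FPKM (SD, n = 3) in siControl and 7.36 ± 0.522 FPKM in siOTUD4, so that 62.5% remained. The log2 fold change was -0.61 ± 0.05 (SE, limma adjusted p = 2.18e-06), and the exact two-sided permutation test gave p = 0.1, the smallest possible for 3 against 3. Of the 11212 genes tested, 5112 had a lower log2 fold change than OTUD4, and the log2 fold change of OTUD4 relative to the median gene was -0.12. The call was lost with median-of-ratios size factors (-0.04, adjusted p = 0.479), and the sign turned with quantile normalization (0.09) and with the longest-transcript GC and length correction (0.025). The fall was larger after TPM rescaling (-1.143, adjusted p = 1.7e-08), where the median gene was at -1.0, and with the median-transcript GC and length correction (-0.906, adjusted p = 1.67e-07), where it was at -0.005.

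**Figure D1:**
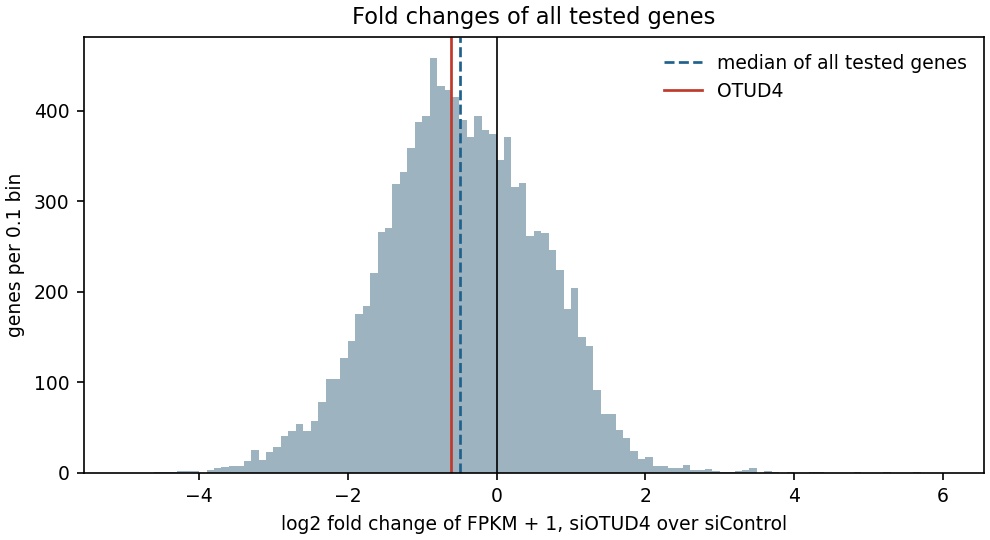
Number of tested genes (y axis, per bin of 0.1) by log2 fold change of FPKM + 1, siOTUD4 over siControl (x axis). The median of all 11212 genes (dashed line) lies at -0.49 and OTUD4 (red line) at -0.61, at the 45.6th percentile of the genes.

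Across the transcriptome, 3295 genes were higher and 7011 lower in siOTUD4, of which 924 were at least 2-fold higher and 3460 at least 2-fold lower (limma, adjusted p under 0.05). The median gene had a log2 fold change of -0.49. The share of lower genes among those called was 68.0% as deposited, 84.4% after TPM rescaling, 47.0% with median-of-ratios size factors, 48.7% after quantile normalization, and 50.1% and 50.5% with the 2 GC and length corrections. The median of all genes moved to -1.0, 0.07, 0.02, -0.005 and -0.009 under these scalings, so the medians of gene lists are given relative to the median gene.

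Transcript length and GC content moved with the fold changes. When genes were ranked by the length of their longest transcript, the lowest quintile, 75 to 1930 nucleotides, had a median log2 fold change of 0.47, and the highest quintile, 5700 to 34500 nucleotides, one of -0.85. From the lowest to the highest quintile of GC content the median went from -0.27 to -0.985. In the quintile of longest transcripts 41.7% of genes were at least 2-fold lower and 1.7% at least 2-fold higher, without regard to the test. Over all genes, GC content and length accounted for 33.8% of the variance of the log2 fold changes with the longest transcript and for 20% with the median transcript.

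**Figure D2:**
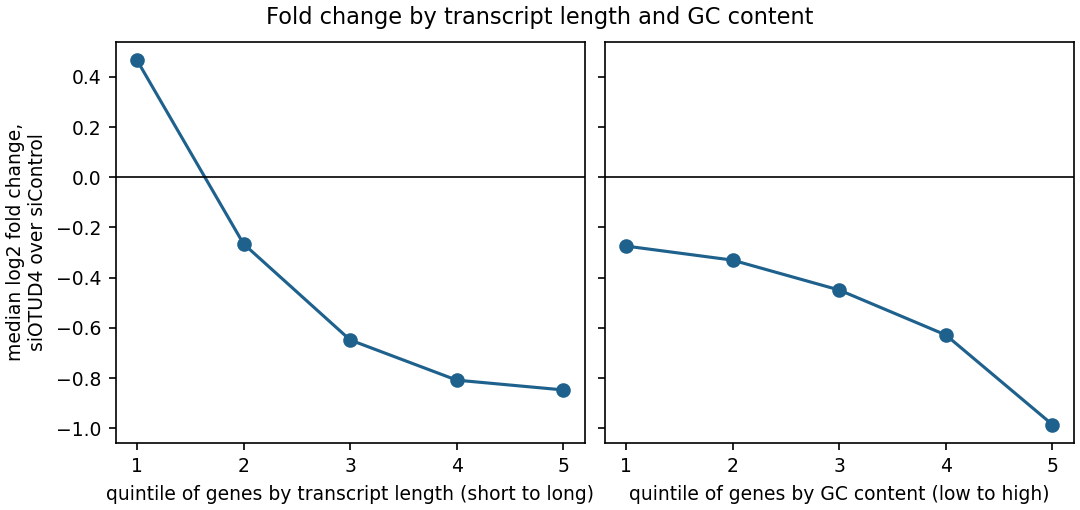
Median log2 fold change (y axis, siOTUD4 over siControl) of tested genes in quintiles of the length of the longest protein-coding transcript (left) and of its GC content (right), each holding 2234 or 2235 genes. The median goes from 0.47 to -0.85 with length and from -0.27 to -0.985 with GC content.

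Of the 8 genes named in advance for the Hippo/YAP axis, ANKRD1 alone was higher in siOTUD4 and the other 7 were lower as deposited, with calls for YAP1, LATS1, CCN1 and OTUD4 that did not hold in every scaling. YAP1 (chromosome 11, 102110461 to 102233423) and WWTR1, which encodes TAZ (chromosome 3, 149517235 to 149736714), are the coactivators that the pathway restrains. YAP1 went from 21.6 ± 0.506 to 13.4 ± 1.07 FPKM (log2 fold change -0.66, adjusted p = 1.78e-06). WWTR1 went from 41.6 ± 1.12 to 15.0 ± 0.201 FPKM (-1.41, adjusted p = 2.97e-10). CCN2 (chromosome 6, 131948176 to 131951373), a target of both coactivators, went from 8.86 ± 0.314 to 2.48 ± 0.418 FPKM (-1.51, adjusted p = 6.31e-08). CCN1, another such target, went from 26.0 ± 0.652 to 18.0 ± 0.333 FPKM (-0.51, adjusted p = 4.18e-07). ANKRD1 (chromosome 10, 90912096 to 90921276), a further target, went from 0.163 ± 0.110 to 3.62 ± 0.357 FPKM (1.99, adjusted p = 1.51e-08). Of the kinases upstream of YAP, LATS2 fell from 7.07 ± 0.195 to 2.04 ± 0.205 FPKM (-1.41), whereas LATS1 went from 6.83 ± 0.116 to 5.85 ± 0.434 FPKM (-0.19, adjusted p = 0.00928). WWTR1, CCN2 and LATS2 were lower under the 5 other scalings too. YAP1 did not pass the threshold with median-of-ratios size factors (-0.06) and was at 0.019 with the longest-transcript correction, CCN1 turned to 0.1 with median-of-ratios size factors and 0.03 with the median-transcript correction, and LATS1 turned to between 0.35 and 0.64 under 4 scalings.

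**Figure D3:**
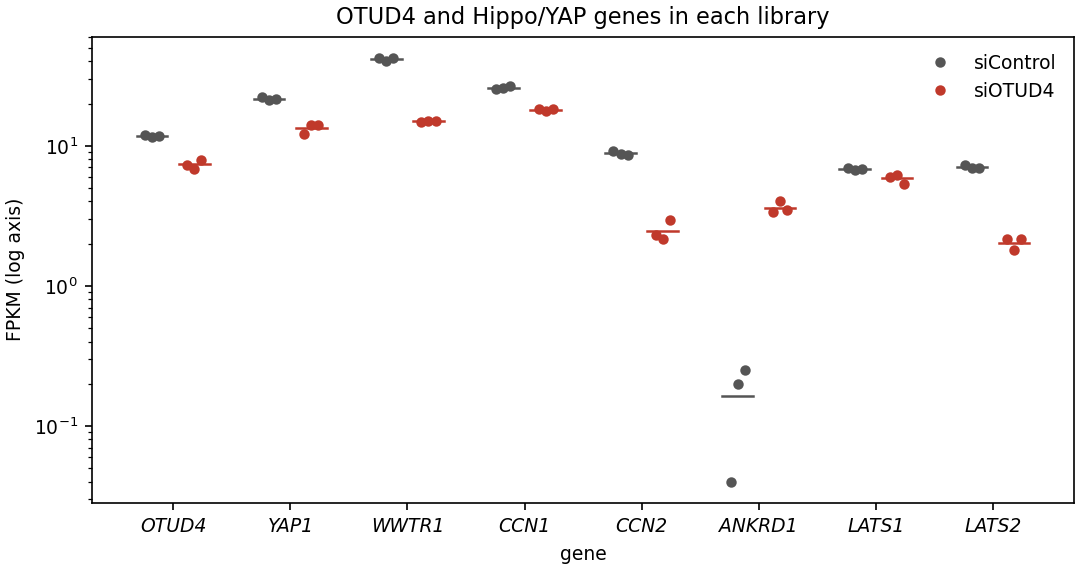
FPKM (y axis, log scale) of OTUD4 and 7 Hippo/YAP genes in each siControl (grey) and siOTUD4 (red) library, with points for libraries and lines for group means, as deposited. ANKRD1 is higher in the siOTUD4 libraries, at 3.36 to 4.03 FPKM, and the other genes are lower, of which OTUD4, YAP1, LATS1 and CCN1 change sign in at least 1 other scaling.

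Most YAP/TAZ targets were lower in siOTUD4, but the list did not pass the test against other genes. Of the 20 tested members 17 fell as deposited, 14 of them at least 2-fold, and 3 rose. CRIM1, a transmembrane protein that binds bone morphogenetic proteins, fell 7.3-fold, from 73.9 ± 1.10 to 10.1 ± 0.758 FPKM. IGFBP3, a binding protein of insulin-like growth factors, fell 6.29-fold, from 185.5 ± 3.43 to 29.5 ± 0.336 FPKM, and FOXF2, a forkhead transcription factor, fell 5.16-fold. The 3 that rose were GADD45A, which is also induced by DNA damage and other stress (13.7 ± 0.722 to 150.6 ± 1.64 FPKM, 11-fold), ANKRD1 and RBMS3 (0.19). The list's median log2 fold change was -1.46, or -0.97 relative to the median gene (camera adjusted p = 0.0621, and adjusted p = 0.183 with an estimated correlation). The list's median stayed below that of all genes in each scaling, at -0.53 to -1.06 relative to it. The camera adjusted p was 0.0093 with median-of-ratios size factors, 0.0194 with quantile normalization and 0.026 with the longest-transcript correction. It was 0.282 after TPM rescaling and 0.076 with the median-transcript correction.

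Hippo pathway components were lower as a list. Of the 26 tested members 23 fell, 17 of them at least 2-fold. The scaffold WWC1 (KIBRA) fell 9.54-fold, from 24.9 ± 0.921 to 2.61 ± 0.0379 FPKM, and the kinase TAOK2 8.82-fold, from 8.59 ± 0.406 to 0.973 ± 0.146 FPKM. AMOTL2, an angiomotin family member, fell 5.11-fold, and LIMD1, a LIM domain protein that binds LATS, 4.81-fold. TEAD4, a DNA-binding partner of YAP (0.35), and NF2, an upstream activator of the pathway (0.36), rose as deposited, and MAP4K4 was at 6.97 and 6.92 FPKM. The median was -0.77 relative to that of all genes (camera adjusted p = 0.0117), and the call was lost with an estimated correlation, where the adjusted p = 0.112. The list's median was negative in each scaling, with 0 members higher and 27 lower after TPM rescaling, 5 higher and 20 lower with median-of-ratios size factors and with quantile normalization, and 5 higher and 19 lower and 4 higher and 19 lower with the median- and longest-transcript corrections.

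Genes of stress responses lay above the median gene in siOTUD4 as deposited. Of 24 genes of the integrated stress response, 16 rose and 7 fell, with a median of 0.97 (1.46 above the median gene, camera adjusted p = 0.000294, and adjusted p = 0.112 with an estimated correlation). DDIT3 (CHOP), a transcription factor of this response, rose 11.1-fold, from 66.3 ± 1.91 to 735.6 ± 21.2 FPKM. ATF3 rose 7.41-fold and ASNS, asparagine synthetase, 7.53-fold. SLC7A5, an amino acid transporter of the same list, fell 10.2-fold, from 516.5 ± 6.08 to 50.8 ± 1.45 FPKM. Of 20 endoplasmic reticulum chaperones and related genes, 12 rose and 7 fell (0.71 above the median gene, camera adjusted p = 0.00532, and adjusted p = 0.258 with an estimated correlation). HSPA5, the main chaperone of that compartment, rose 5.86-fold, from 309.6 ± 2.83 to 1812.9 ± 38.5 FPKM, HERPUD1 6.7-fold and XBP1 5.06-fold. Both calls were lost with an estimated correlation and with quantile normalization (adjusted p = 0.0637 for the integrated stress response and adjusted p = 0.545 for the chaperones), and the chaperones' median was -0.35 after TPM rescaling, still 0.649 above the median gene.

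Targets of p53 and NF-kB lay above the median gene as lists, in calls that were lost with an estimated correlation. Of 22 p53 targets 16 rose, and XPC, TNFRSF10B, FDXR and SESN2 fell. GDF15, a secreted factor that is also induced by the integrated stress response, rose 20.5-fold, from 57.1 ± 1.62 to 1169.6 ± 43.5 FPKM. TP53I3 rose 4.69-fold, the pro-apoptotic PMAIP1 3.64-fold and AEN 3.58-fold. The p53 list lay 1.05 above the median gene (camera adjusted p = 0.000265, and adjusted p = 0.112 with an estimated correlation), and 0.992 above it after TPM rescaling, where its median was -0.008. Of 13 NF-kB targets 9 rose and TNFAIP2, TNIP1, NFKB2 and TNFAIP3 fell (1.15 above the median gene, camera adjusted p = 0.00579, and adjusted p = 0.112 with an estimated correlation). RELB, a subunit of NF-kB, went from 1.33 ± 0.291 to 8.66 ± 0.367 FPKM, and the inhibitor NFKBIA and the mitochondrial dismutase SOD2 rose 3.55-fold and 2.98-fold. The NF-kB call was also lost with a filter at 5 FPKM (adjusted p = 0.0803).

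Cholesterol synthesis and MYC target lists lay above the median gene with members in both directions. Of 24 cholesterol genes 14 rose and 7 fell (0.86 above the median gene, camera adjusted p = 0.00532, and adjusted p = 0.112 with an estimated correlation). The synthesis enzymes MSMO1 and ACAT2 rose 3.86-fold and 2.86-fold, whereas SREBF2, a regulator of the pathway, fell 3.29-fold. Of 25 MYC targets 15 rose and 9 fell (0.72 above the median gene, camera adjusted p = 0.0117, and adjusted p = 0.112 with an estimated correlation). The nucleolar protein NOP56 and ODC1, of polyamine synthesis, rose 2.27-fold and 2.18-fold, and TCOF1 and CAD fell 4.34-fold and 3.48-fold. MYC itself, listed under ERK pathway output, fell 4.56-fold, from 140.3 ± 1.01 to 30.8 ± 0.334 FPKM. After TPM rescaling the medians of the 2 lists were negative (-0.21 and -0.34) and lay 0.789 and 0.655 above the median gene. The MYC call was also lost with TPM rescaling (adjusted p = 0.156), quantile normalization (adjusted p = 0.491) and a filter at 5 FPKM (adjusted p = 0.0693).

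Hypoxia and glycolysis genes lay below the median gene without passing the test. Of 22 members 17 fell, 13 at least 2-fold, and ADM, GAPDH, TPI1 and ALDOA rose as deposited (median -0.72 relative to the median gene, camera adjusted p = 0.0623, and adjusted p = 0.183 with an estimated correlation). PFKFB4, a regulator of glycolysis, fell 14.2-fold, from 43.4 ± 1.01 to 3.06 ± 0.152 FPKM, the prolyl hydroxylase EGLN3 14.9-fold, and NDRG1 5.69-fold, from 785.5 ± 1.73 to 138.1 ± 2.21 FPKM. The list passed the camera threshold under each of the 5 other scalings, with adjusted p from 1.12e-06 to 0.039, and its median was negative in each. Of 15 ERK pathway genes 11 fell, among them EGR1, and 4 rose (camera adjusted p = 0.519). Of 20 actin cytoskeleton and SRF genes 12 fell and 6 rose (camera adjusted p = 0.862), and the list passed with quantile normalization alone (adjusted p = 0.00367, -0.934 relative to the median gene). The filament crosslinker FLNA fell 6.47-fold, from 197.3 ± 3.03 to 30.5 ± 1.27 FPKM, the adaptor TLN1 10.4-fold and SRF itself 5.76-fold.

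Cell cycle genes moved both ways. Of 43 S phase genes 11 rose and 29 fell as deposited, while with median-of-ratios size factors 23 rose and 15 fell (camera adjusted p = 0.742 as deposited, and 0.0263 with quantile normalization, where the median lay 0.348 below that of all genes). UHRF1, a maintenance factor of DNA methylation, fell 6.28-fold, and cyclin CCNE2 4.4-fold, whereas the centromere protein CENPU rose 3.96-fold. Of 54 G2/M genes 21 rose and 29 fell as deposited, and 37 rose and 15 fell with median-of-ratios size factors (camera adjusted p = 0.38 as deposited and 0.0336 with median-of-ratios size factors). CDC20, an activator of the anaphase-promoting complex, rose 3.16-fold and the condensin subunit NCAPD2 fell 3.21-fold. The G2/M list had a median of -0.20 and a mean of -0.15, while its camera direction was up. Of 23 interferon-stimulated genes 10 rose and 10 fell as deposited (camera adjusted p = 0.104), 15 rose and 5 fell with median-of-ratios size factors, 17 rose and 4 fell with quantile normalization (camera adjusted p = 0.0196), and 7 rose and 14 fell after TPM rescaling. The interferon list also passed with no filter on low values (adjusted p = 0.037). ISG15, a ubiquitin-like modifier, rose 12.6-fold, from 176.3 ± 18.3 to 2228.8 ± 74.2 FPKM, and IFIT2 3.28-fold, whereas STAT2 fell 3.85-fold. Of 13 OTU deubiquitinases 9 fell, including OTUD4 and OTULIN (3.27-fold), and OTUB1, YOD1 and ALG13 rose (camera adjusted p = 0.993). That list's median was -0.40 as deposited and positive under 4 other scalings, and its camera direction was down although its median lay 0.10 above that of all genes.

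Epithelial, mesenchymal and basal-like tumour genes did not pass camera, the comparison with other genes, as deposited. Fry, which makes no such comparison, passed for each of the 19 lists except interferon-stimulated genes (fry adjusted p = 0.104). Its passes include YAP/TAZ targets (down, fry adjusted p = 1.24e-08) and are thus not particular to the lists here. The epithelial list passed fry upwards (fry adjusted p = 0.00212). The mesenchymal (fry adjusted p = 4.24e-08) and basal-like lists (fry adjusted p = 0.000351) passed it downwards. Of 12 tested epithelial genes 7 rose and CLDN7, TJP1, ESRP2, MUC1 and ST14 fell (camera adjusted p = 0.0623, and adjusted p = 0.346 with an estimated correlation), and the list passed with TPM rescaling (adjusted p = 0.00912) and with the longest-transcript correction (adjusted p = 0.026). Keratin KRT7 rose 3.44-fold, from 114.0 ± 2.29 to 392.4 ± 17.6 FPKM, and the membrane protease ST14 fell 9.06-fold. Of 14 mesenchymal genes 9 fell and VIM, LGALS1, SNAI1 and SNAI2 rose as deposited (camera adjusted p = 0.88, direction down although the median lay 0.25 above that of all genes). Fibronectin, FN1, fell 15.0-fold, from 14.3 ± 0.235 to 0.953 ± 0.0737 FPKM, and the lysyl oxidase LOXL2 7.52-fold. Of 9 basal-like tumour genes 4 rose, including S100A2 (4.9-fold), and 5 fell, including TNS4 (10.4-fold, camera adjusted p = 0.487, direction up with a median of -0.08). None of the 16 classical pancreatic tumour genes listed reached the mean of 1 FPKM, and their highest value in any library was 1.27 FPKM, for SPINK4.

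Markers of cell types that a cell line culture should lack were examined in the same way. The 4 tested fibroblast markers fell in siOTUD4, COL5A1 19.3-fold from 98.9 ± 0.377 to 5.11 ± 0.117 FPKM, COL1A1 14.7-fold, PDGFRB 6.95-fold and FBLN1 2.12-fold (camera adjusted p = 0.0623, and adjusted p = 0.373 with an estimated correlation). They passed the camera threshold with each scaling except TPM. The other fibroblast markers listed, COL1A2, DCN and THY1, stayed at or below 0.15 FPKM in all 6 libraries. The 4 that fell therefore do not show that fibroblasts were present. The leukocyte markers CD68 and CSF1R and the endothelial markers ERG and EGFL7 were the only tested members of their lists. CD68, also a lysosomal protein of other cells, rose from 9.39 ± 1.26 to 24.6 ± 0.425 FPKM and EGFL7 fell from 57.7 ± 1.23 to 24.1 ± 0.765 FPKM. The EGFL7 call was lost with the longest-transcript correction (-0.07, adjusted p = 0.109). CSF1R and ERG stood at 1.93 and 4.30 FPKM in siControl and changed sign with the scaling. The epithelial genes CDH1, KRT19 and RAB25 stayed at or below 0.87 FPKM in all 6 libraries and EPCAM at or below 2.32 FPKM.

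**Figure D4:**
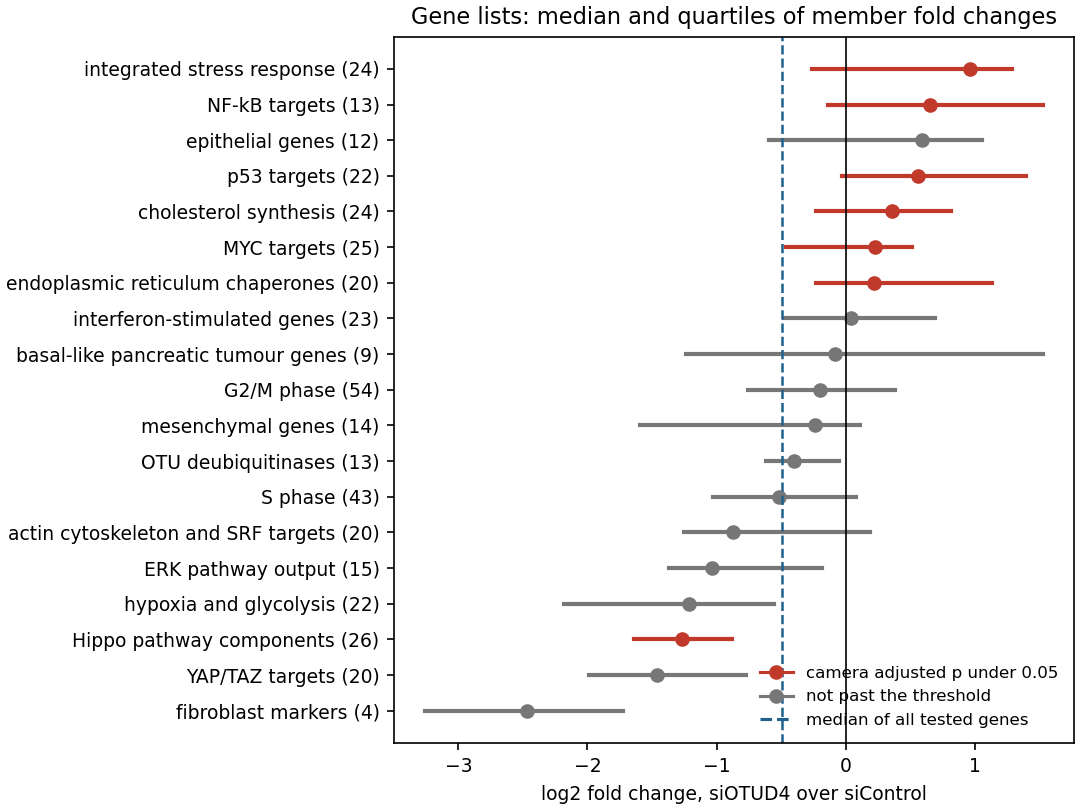
Median (points) and quartiles (bars) of the log2 fold changes of tested members of 19 gene lists (x axis, siOTUD4 over siControl, number of members in brackets), as deposited, with the median of all genes at -0.49 (dashed). Lists in red passed camera with the preset correlation but none of them with an estimated correlation (adjusted p from 0.112 to 0.258). Of these, Hippo pathway components are lower, and the medians of the endoplasmic reticulum chaperone, p53, cholesterol and MYC lists turn negative after TPM rescaling while staying 0.649 to 0.992 above the median gene. Medians of the cell cycle, interferon, OTU, basal-like and mesenchymal lists also change sign between scalings.

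The metallothionein MT1E rose 49.0-fold, from 113.6 ± 7.57 to 5564.1 ± 359 FPKM, and MT1F 41.3-fold, from 1.54 ± 1.39 to 63.5 ± 1.12 FPKM. The siControl libraries had MT1F at 0.5, 1 and 3.11 FPKM, and leaving out each in turn gave log2 fold changes of 4.491 to 5.218, so the size of its rise is uncertain. The stress-inducible chaperones HSPA1B and HSPA1A rose 18.9-fold and 16-fold, HSPA6 30.5-fold from 0.687 ± 0.148 FPKM, and the co-chaperone DNAJB1 12.8-fold. Reads of the metallothioneins, of HSPA1A and HSPA1B, and of histone genes are shared with near-identical copies, so the split between them is uncertain. The histone gene H4C11 was listed at 0 in the 3 siControl libraries and at 33.71, 33.46 and 41.84 FPKM in the siOTUD4 libraries. TMEM265 and DHRS2 rose 21.3-fold and 15.8-fold from levels of 0.930 and 1.92 FPKM, and GDF15, ISG15 and DDIT3 were the others among the 12 genes with the largest rises. Their log2 fold changes were at least 2.62 in all scalings.

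NOTCH3, a Notch receptor, fell 70.5-fold, from 29.4 ± 0.648 to 0.417 ± 0.0289 FPKM (log2 fold change of FPKM + 1 of -4.42). TTYH3, a chloride channel family member, fell 49.6-fold, from 44.3 ± 0.829 to 0.893 ± 0.0802 FPKM. The lipid transporter ABCA2, EHBP1L1, the immunoglobulin superfamily member IGSF8 and the endocytic receptor LRP1 fell 34.8-fold to 39.4-fold. SLC29A4, HR, COL5A1 and NPTX1 fell 15.9-fold to 27.9-fold. MTRNR2L1 and MTRNR2L9, nuclear genes that resemble the mitochondrial 16S ribosomal RNA and can share its reads, fell 21.9-fold and 19.2-fold. Their log2 fold changes were at most -1.95 in all scalings. Counts of members adjusted over the list alone were identical to those over all genes tested for each of the 22 lists.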

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

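The GC and length corrections were chosen after seeing the data, the longest-transcript one after OTUD4 had been seen under the other, and the remaining alternatives before. Depth is unknown, so its limit on weakly expressed genes was not measured. Against 3295 higher and 7011 lower genes, rescaling gave 1661 higher (TPM), 5338 (median-of-ratios) and 5061 (quantile). Of the genes higher as deposited, 1005 were lower after TPM rescaling, 195 after quantile normalization, and 27 and 289 with the median- and longest-transcript corrections, and of those lower as deposited, 1156 were higher with median-of-ratios, 1341 with quantile normalization, and 1217 and 1435 with the corrections. Against 924 genes at least 2-fold higher, counts were 240 (TPM), 2341 (median-of-ratios), 1423 (quantile) and 1557 (median-transcript correction). Against 3460 at least 2-fold lower, they were 2175 (filter at 5 FPKM, where fewer genes were tested), 5662 (TPM), 1781 (median-of-ratios), 1500 (quantile), 1519 and 1208 (median- and longest-transcript corrections). By construction TPM and median-of-ratios multiply a whole library by one factor, and the corrections remove a trend with GC content and length. Quantile normalization changes genes unequally. OTUD4 was at -0.04 with median-of-ratios, 0.09 with quantile normalization, 0.025 with the longest-transcript correction, and -0.906 with the median-transcript one. The list of Hippo components kept its call except with an estimated correlation (-0.774 relative to the median gene, adjusted p = 0.112). YAP/TAZ targets passed with no filter (-1.227), a filter at 5 FPKM (-1.389), median-of-ratios (-1.059), quantile normalization (-0.741) and the longest-transcript correction (-0.527). For these lists, the cause was not tested.

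Single genes that turned sign were CCN1 (0.1 with median-of-ratios, 0.03 with the median-transcript correction), CSF1R (0.151 median-of-ratios, 0.685 quantile, 0.118 and 0.882 with the median- and longest-transcript corrections), LATS1 (0.354, 0.642, 0.448 and 0.417 in the same order), OTUD7B (0.005 quantile, 0.098 and 0.03 with the corrections), ERG (0.012 quantile) and YAP1 (0.019, longest transcript). The cause was not tested. Among other named genes and lists, 16 comparisons lost a call and 18 gained one, while 1925 kept their side of the threshold. The latter include changes of direction without a call in either setting, as for OTU deubiquitinases with the median-transcript correction.

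No pairing by replicate name was visible. Deviations of same-named libraries correlated at -0.085, 0.043 and 0.001, and those of differently named ones at -0.118 to 0.109. Such values cannot tell whether same-named libraries were handled together, which the labels do not say. With the name as a block, 3281 genes were higher and 6995 lower, OTUD4 stayed at -0.613, and YAP/TAZ targets and Hippo components kept their side of the threshold. Leaving out 1 library at a time gave 3215 to 3250 higher and 6831 to 7051 lower genes, 895 to 932 and 3373 to 3507 at least 2-fold, and OTUD4 at -0.659 to -0.57. The lists of YAP/TAZ targets (-1.027 to -0.944) and Hippo components (-0.81 to -0.74) kept their side of the threshold.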

Other observations

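The gene families, the stress lists, the splits, the GC and length, abundant-gene and epithelial-gene tests were chosen after the results they concern had been seen, and the test of OTUD4 against similar genes after its fold change, the median gene and the median-transcript correction had been seen, but before its percentiles were. Several families, set by gene symbol with paralogs included, were higher in siOTUD4 as deposited, with medians above 0 in each of the 6 scalings but smaller against the median gene once GC content and length were corrected. Of 82 ribosomal protein genes 81 were higher and RPL7L1 was lower, with a median 1.55 above the median gene, 1.04 and 0.474 above it with the median- and longest-transcript corrections, and 0.109 with quantile normalization, where 48 were higher and 19 lower. Of 75 respiratory chain subunits 70 were higher, and COX6B2, NDUFA4L2 and NDUFC2 were lower (1.204 above the median gene, 0.76 and 0.269 with the corrections, the latter with 45 higher and 27 lower, and 0.198 with quantile normalization, with 47 higher and 20 lower). Of 41 proteasome subunits 37 were higher, PSMC1 3.75-fold and PSMD14 3.25-fold, and PSME4, PSMD5, PSMD12 and PSMD3 were lower (1.55 above the median gene, and 0.71 with the longest-transcript correction). Of 78 mitochondrial ribosomal proteins 65 were higher, and MRPS25, MRPS27, MRPL16 and MRPL50 were lower (1.24 above the median gene, and 0.554 with that correction). Of 41 replication-dependent histone genes 28 were higher, and H4C9, H2AC15, H2AC11 and H2BC17 were lower (1.66 above the median gene, and 0.534 with that correction, where the camera call was lost, adjusted p = 0.126). After TPM rescaling, in the order given, 76, 41, 30, 43 and 24 members were higher and 5, 22, 10, 24 and 10 lower. With an estimated correlation camera gave an adjusted p of 0.0389 for the proteasome and of 0.0368 for each of the other 4 families.

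Metallothioneins, which bind zinc and copper, were higher in 5 of 5 tested genes, with MT2A at 774.8 ± 26.6 in siControl and 7744.9 ± 398 FPKM in siOTUD4. Of 24 heat shock proteins 19 were higher, and HSPA2, HSPA12A, HSPA1L, HSPB7 and HSPA14 were lower (1.285 above the median gene, and 0.493 with quantile normalization), and after TPM rescaling 14 were higher and 9 lower. Of 14 collagens 13 were lower, COL18A1 from 23.6 ± 0.514 to 0.820 ± 0.110 FPKM, and COL16A1 was higher (camera adjusted p = 0.0026, and adjusted p = 0.041 with an estimated correlation). The collagens' median lay 2.33 below the median gene as deposited and 1.51 and 1.27 below it with the median- and longest-transcript corrections. All 9 tested integrins were lower as deposited, ITGB4 from 14.2 ± 0.560 to 0.740 ± 0.320 FPKM (camera adjusted p = 0.00644, and adjusted p = 0.0584 with an estimated correlation), while 1 was higher with quantile normalization and 1 with the median-transcript correction. Of 7 laminins 6 were lower and LAMA3 was higher, without passing the test as a family as deposited (camera adjusted p = 0.0535, and adjusted p = 0.129 with an estimated correlation). The laminins passed with median-of-ratios size factors (adjusted p = 0.00916), quantile normalization (adjusted p = 0.0101) and the median-transcript correction (adjusted p = 0.0398), and their median went from 1.16 below the median gene to 0.353 and 0.372 below it with the corrections. The 5 genes resembling mitochondrial 16S ribosomal RNA were lower, MTRNR2L8 from 3660.9 ± 26.3 to 388.4 ± 10.7 FPKM (camera adjusted p = 0.0199, adjusted p = 0.167 with an estimated correlation, and adjusted p = 0.0587 after TPM rescaling).

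The count of 10306 genes past the threshold was reached by 1 of the 10 splits of the 6 libraries into 3 and 3, the real one. The count of 4384 genes changed at least 2-fold was likewise reached by 1 split. The highest count in any other split was 0 for both by limma, and 4 and 2 genes at an unadjusted p under 0.05. With 10 splits the share cannot fall under 0.1. Each other split mixes libraries of both groups, so the group difference enters the spread within its groups. Their low counts follow from that and are no separate support.

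Long and GC-rich genes were lower in siOTUD4 across the transcriptome. The fitted trend with GC content and length did not take up the whole of the difference. After the longest-transcript correction 2485 genes still differed at least 2-fold, against 4384 before. Those at least 2-fold lower went from 3460 to 1208, and those at least 2-fold higher from 924 to 1277. The fit used annotated transcripts, which may not be those expressed, so it cannot exclude a length or GC bias as the whole cause. A larger share of a few abundant genes alone would shift all others by one factor, and 4122 genes differed at least 2-fold after median-of-ratios scaling. Different cells in the 2 groups would give many genes present in one group only, and 1 gene, H4C11, had a mean of at least 10 FPKM in one group and at most 0.1 in the other. RNA quality or library preparation that differed between the groups, toxicity of the siRNA and an effect of OTUD4 loss may each contribute and stay open, untested, because the labels give nothing that varies within a group.

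OTUD4 fell by about as much as the median of all genes as deposited. Among the 200 tested genes nearest to it in length, GC content and siControl level, its fold change lay at the 29.5th percentile with the median transcript (1255 nucleotides), where those genes had a median of -0.062, and at the 51.0th with the longest (7273 nucleotides), where they had one of -0.622. The fall may therefore be a share of the broad shift, and a specific knockdown that is hidden in it stays open. OTUD4 was at -0.906 with the median-transcript correction and at 0.025 with the longest-transcript one, so the answer depends on which transcript stands for the gene. Protein levels were not analysed here.

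Several epithelial and pancreatic genes were near 0 in all 6 libraries. The highest siControl value of CDH1, KRT19, EPCAM and RAB25 was 1.46 FPKM, for EPCAM. Those 4 were chosen because they were near 0, whereas 8 of the 19 epithelial genes listed had a siControl mean of at least 10 FPKM, with KRT8 at 393.4 ± 2.67, KRT18 at 467.7 ± 4.25, KRT7 at 114.0 ± 2.29, CLDN7 at 47.3, ELF3 at 43.7, CLDN4 at 24.4, MUC1 at 20.7 and ST14 at 18.3 FPKM. The 16 listed classical pancreatic tumour genes, fixed before the data were examined, were not picked for being low. None of them exceeded 1.27 FPKM in any library. GRHL2 and OVOL1 of the epithelial list also stayed at or below 0.08 FPKM. Among mesenchymal genes, VIM was at 909.3 ± 12.2, SNAI2 at 25.1 and ZEB1 at 10.2 FPKM in siControl. CDH2, ZEB2, MMP2, TNC and CDH11 of that list stayed at or below 0.54 FPKM in all 6 libraries. Whether the cells were other than the labelled line stays open. The 4 genes picked for being low cannot test it. No reference profile of AsPC-1 was used here, so the low classical genes cannot decide it either. Values near 0 may also be failed estimates of single genes, which stays open, and no biological explanation was tested.

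A hypothesis for the chaperone and metallothionein rise is a response to damaged protein or to oxidants and metals, tested on lists written before their own values were seen. All 12 heat shock factor targets outside the heat shock family were higher as deposited, with a median 1.35 above the median gene (camera adjusted p = 4.84e-07, and adjusted p = 0.0128 with an estimated correlation), and after TPM rescaling 7 were higher and 4 lower. Their median lay 0.941 above the median gene with the median-transcript correction and 0.724 with quantile normalization, under the 1 set beforehand. The 12 targets include DNAJB4, of the same DNAJB family as DNAJB1, so the list is not wholly separate from the chaperone genes that prompted it. Of 15 NRF2 targets 12 were higher, among them NQO1 and the ferritin genes FTL and FTH1, and GCLC and SRXN1 were among those lower (median 1.085 above the median gene, camera adjusted p = 2.67e-05, and adjusted p = 0.0128 with an estimated correlation), and after TPM rescaling 7 were higher and 5 lower, and the call was lost with quantile normalization (0.897 above the median gene, adjusted p = 0.0522). As deposited, both lists moved in the direction of such responses. Ribosomal proteins (1.546), mitochondrial ribosomal proteins (1.242) and respiratory chain subunits (1.204) also lay more than 1 above the median gene. The as-deposited medians alone therefore cannot tell such responses from a wider rise. With the longest-transcript correction these families lay 0.474, 0.554 and 0.269 above the median gene, the heat shock factor targets 1.084 and the NRF2 targets 1.02. Whether OTUD4 loss or another effect of the siRNA against it would start them was not tested. Transfection itself was common to both groups.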
